A study of Gymnopus androsaceus with 9 samples.

How the data were processed

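Total RNA from Gymnopus androsaceus mycelium on pine needle litter was sequenced as paired-end Illumina libraries, per the labels' protocols, with 3 biological replicates at each of 3 harvests. The authors deposited one table per library, each listing the same 29375 JGI protein IDs. Per the file headers, each table gives the count of unique gene reads, the count of total gene reads and an RPKM value for every gene. The deposited RPKM values were checked against the deposited counts: total gene reads divided by RPKM and by the column sum gave the same whole-number transcript length for each of 25486 genes in every library where the gene had reads, within 0.01 bases, so the authors' RPKM is scaled to the sum of total gene reads. The implied lengths ran from 149 to 13812 bases with a median of 1011. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here, and no reference genome was used.

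Unique gene reads were analysed as counts, because reads shared between genes cannot be assigned to one of them. This choice was made after the tables were seen and before any test was run, and total gene reads were tried as an alternative. Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr low-count filter and robust quasi-likelihood fits. All 9 libraries entered one fit with no covariate and 6 residual degrees of freedom, so that the harvests shared one estimate of spread. A difference was called at a Benjamini-Hochberg adjusted p under 0.05. The filter left 20168 genes to test and set aside 9207. Contrasts compared 5 with 2, 10 with 5 and 10 with 2 months, and an F test on 2 coefficients tested any difference among the 3 harvests. The SE of a log2 fold change was obtained as its size divided by the square root of the F statistic, so it is the error implied by the test. CPM values of named genes were scaled with the TMM factors, which ran from 0.596 to 1.19, while percent shares are plain percentages of unique gene reads. Where a gene had between 1 and 3 reads at a harvest, an exact 95% binomial interval was computed for the scaled ratio of reads.

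The rule for named genes was fixed before the data were examined. As IDs were not paired with product names, it took per comparison the 2 genes that rose and the 2 that fell most among those called, with a mean of at least 10 CPM in the higher harvest and no overlap between the 3 and 3 libraries, and once the 5 genes with the highest mean CPM. A set of 34 lists of gene families, also fixed beforehand and defined by product names, found 0 members for the same reason, so list tests and list shares were not run. The 6 co-varying abundant genes were defined after the data were seen, by a correlation over 0.95 with the most abundant gene on log2(CPM + 0.5) among 16606 genes over 1 CPM.

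The edgeR step was tested on simulated data with 200 genes changed among 20168, all drawn from genes with a mean over 1 CPM. It recovered 46% of 2-fold and 96% of 4-fold changes for 5 against 2 months, 32% and 96% for 10 against 5 months, and 44% and 88% for 10 against 2 months. Among called genes 6.58%, 7.91% and 2.94% were false in the same order. Recovery of rarer genes was not tested. Far more genes were called in the real data than were changed here, so these shares may not carry over to it. Chance sharing between comparisons with libraries in common was estimated from 20 simulations of unchanged groups. Alternatives were other scaling methods, other filters, DESeq2 1.42.0, limma voom 3.58.1, a fit with only the compared harvests, a 2-fold minimum, replicate number as a block, and each library left out in turn. Alternatives added after seeing the data were total gene reads, upper-quartile scaling, library totals with no further scaling, libraries thinned to one depth, the 6 genes left out of the counts, and the 2 or 3 libraries with the highest share of those genes left out. Tables were prepared and figures drawn in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.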

Results

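Transcript levels were measured in mycelium of Gymnopus androsaceus, a litter-decomposing basidiomycete, growing on Scots pine needles. The needles had been mixed with sand, sterilised by radiation and inoculated with a needle already carrying the fungus, and the fungus then grew in sealed vessels. Mycelium was harvested at 2, 5 and 10 months, and the comparisons ask how the transcript pool differed as growth on the litter went on. Each harvest had 3 libraries from 3 biological replicates, 9 libraries in all. The growth protocol gives more microcosms per harvest than there are libraries, and which was not sequenced is not stated. The 2-month libraries held 51907213, 30205968 and 21939600 reads unique to one gene. The 5-month libraries held 61180124, 78159105 and 29885380, and the 10-month libraries 96533143, 81664375 and 60591632. Mean depth was thus lowest at 2 months and highest at 10 months. Of 29375 genes listed, 25486 had a read in at least 1 library, and between 20782 and 22641 had a unique read in a given library. The floor of 3 reads lay between 0.0311 and 0.137 CPM, the read count scaled to library size, and covers counting error only. The deposited tables pair no gene with a name or product, so genes are given by their JGI protein ID, and no statement is made about what they encode.

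The 3 harvests were separated from each other in the leading components of log2 CPM. The first component held 48.7% of the variance and placed the 2-month libraries between -94.7 and -79.3, the 5-month libraries at 11.8 or more, and the 10-month libraries above all of these, at up to 82.5. The second component held 20.2% and set the 5-month libraries, between -68.3 and -49.4, apart from both other harvests, which were all above 0. Spearman correlation across genes was 0.979 to 0.990 for the 9 pairs of libraries from one harvest and 0.958 to 0.982 for the 27 pairs from different harvests. It was taken on unscaled unique reads of all listed genes. Those without reads in any library were included, which can raise all of these values. No pair of libraries agreed within sampling noise, since the lowest chi-square per gene within a harvest was 81.6. The biological coefficient of variation was 29.0% at 2 months, 23.3% at 5 months and 21.7% at 10 months.

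**Figure D1:**
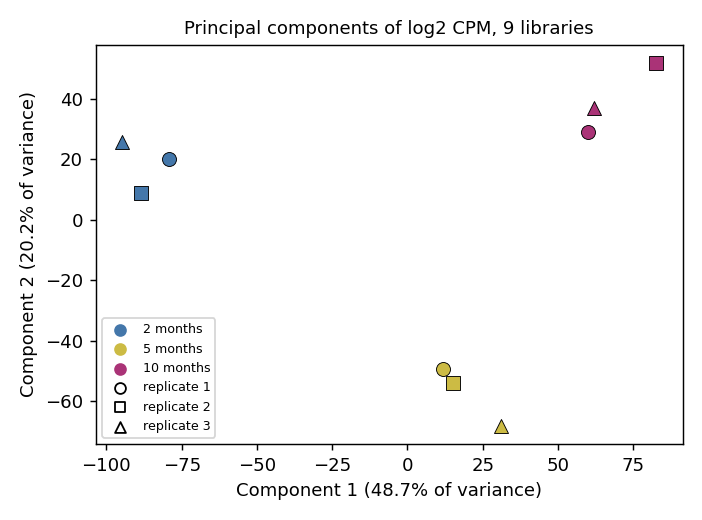
First and second principal components of log2 CPM, with their shares of variance (48.7% and 20.2%) on the axes; each point is 1 of the 9 libraries, coloured by harvest and shaped by replicate number. The 3 libraries of each harvest lie together, and the 5-month libraries are the ones below 0 on the second component.

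Over the 3 harvests, 7746 of 20168 tested genes (38.4%) differed by edgeR's quasi-likelihood F test at a Benjamini-Hochberg adjusted p under 0.05. By mean level, 2836 of them (36.6%) were highest at 2 months, 1903 (24.6%) at 5 months and 3007 (38.8%) at 10 months. The median ratio of the highest to the lowest harvest was 2.10 for genes highest at 2 months, 2.68 for those highest at 5 months and 2.40 for those highest at 10 months. Means stepped upward from 2 through 5 to 10 months in 2104 of the changed genes (27.2%) and stepped downward in 2025 (26.1%). The 5-month mean was the highest in 1184 genes whose lowest mean was at 2 months and in 719 whose lowest was at 10 months. It was the lowest in 811 genes highest at 2 months and in 903 highest at 10 months. At least 2-fold above both other harvests were 623 genes at 2 months, 462 at 5 months and 952 at 10 months. At least 2-fold below both others were 1187 genes at 2 months, 75 at 5 months and 535 at 10 months. These groups rest on means and were not tested one against another. The count fell to 5099 when only genes with at least 10 CPM in 3 libraries were tested. It also fell without the 3 libraries in which 6 genes, described further on, took over 10% of reads. That fit left a single 10-month library, so an effect of those libraries cannot be told apart from the smaller number of libraries.

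Growth from 2 to 5 months was compared to see which transcripts differed between early and middle harvests. Among the genes named by the fixed rule, JGI protein ID 921610 stood at 0.391 ± 0.205 CPM (SD, n = 3) at 2 months and 266 ± 119 CPM (SD, n = 3) at 5 months. Its log2 fold change was 9.45 with an SE of 0.59 (edgeR, adjusted p = 1.2e-05). ID 922432 went from 1.08 ± 1.41 CPM to 578 ± 120 CPM (SD, n = 3 each), a log2 fold change of 9.20 with an SE of 0.99 (edgeR, adjusted p = 0.000379). Without 2-month replicate 3 the log2 fold change of ID 922432 was 10.97 and that of ID 921610 was 9.80, so the order of these rises is not fixed. Both genes kept a high mean at 10 months, at 333 ± 163 and 803 ± 453 CPM (SD, n = 3 each). ID 1026260 fell from 358 ± 189 CPM at 2 months to 1.89 ± 1.27 CPM at 5 months (SD, n = 3 each), with a log2 fold change of -7.52, an SE of 0.62 and an adjusted p of 6.2e-05 by edgeR. ID 960591 fell from 36.1 ± 25.9 CPM to 0.355 ± 0.211 CPM (SD, n = 3 each), with a log2 fold change of -6.79, an SE of 0.70 and an adjusted p of 0.000196 by edgeR; the log2 fold change was -6.01 without 2-month replicate 1. The levels of 3 of these genes are uncertain because many of their reads also map to other genes: 39.9% for ID 922432, 46.3% for ID 1026260 and 32.1% for ID 960591.

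In all, 4180 genes (20.7% of those tested) changed between 2 and 5 months by edgeR, of which 2345 were higher and 1835 lower at 5 months. Among the higher genes, 1710 rose at least 2-fold and 263 at least 8-fold, against 747 and 45 among the lower genes. The median log2 fold change was 1.39 in the higher genes and -0.90 in the lower genes. The higher genes included 18 with 0 unique reads in every 2-month library. All 5-month libraries lay above all 2-month libraries in 2317 of the higher genes and below them in 1784 of the lower genes. Over all tested genes such separation was seen in 37.9%, where chance gives 10% on average. Genes vary together across libraries, so the share in a single comparison can lie well off that average by chance, here and in the comparisons below. Among changed genes with a mean under 1 CPM over the 9 libraries, 307 were higher and 80 lower at 5 months. From 1 to 10 CPM 863 were higher and 681 lower, from 10 to 100 CPM 919 and 937, and over 100 CPM 256 and 137. Scaling to library totals alone, tried after seeing the data, moved the median log2 fold change of all genes from -0.01 to 0.13 and gave 2348 higher and 629 lower genes, or 78.9% higher in place of 56.1%. Without 5-month replicates 1, 2 and 3 in turn the lower genes numbered 1039, 1042 and 1177 in place of 1835, and the higher genes 1805, 1730 and 1757. The total was 2772 without 5-month replicate 2 and 2539 with only genes of at least 10 CPM in 3 libraries.

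**Figure D2:**
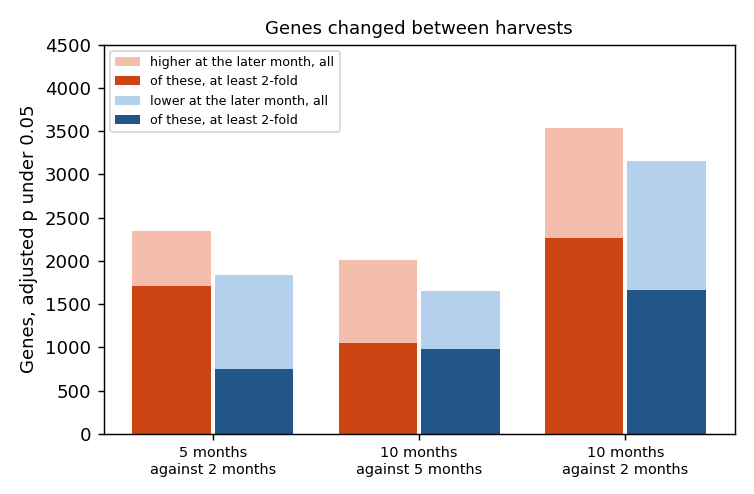
Number of genes with an adjusted p under 0.05 by edgeR in each comparison of harvests; pale bars count the genes higher (red) or lower (blue) at the later harvest and the dark part those changed at least 2-fold. At 5 against 2 months, 1710 higher genes but 747 lower genes reached 2-fold.

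The comparison of 10 with 5 months covered the later part of growth. ID 990777 stood at 0.691 ± 0.345 CPM at 5 months and 86.5 ± 21.7 CPM at 10 months (SD, n = 3 each), a log2 fold change of 6.91 with an SE of 0.41 (edgeR, adjusted p = 3.0e-06). ID 952265 rose from 0.492 ± 0.150 to 29.2 ± 34.8 CPM (SD, n = 3 each), with a log2 fold change of 5.91, an SE of 1.42 and an adjusted p of 0.0251 by edgeR. This call was fragile: leaving out any 5-month library, or 10-month replicate 2, gave adjusted p of 0.0602 to 0.0759, with a log2 fold change of 4.30 in the last case, and limma voom gave 0.221, within a range of 1.2e-05 to 0.243 over its alternatives. Its rise lay in 10-month replicates 1 and 2, at 15.8 and 40.6 unscaled CPM against 1.02 CPM in replicate 3, and these are the 2 libraries of that harvest rich in the 6 genes described further on. Without them and 2-month replicate 2 the log2 fold change was 1.09. ID 1008095 fell from 14.6 ± 2.83 CPM to 0.352 ± 0.141 CPM (SD, n = 3 each), with a log2 fold change of -5.40, an SE of 0.48 and an adjusted p of 3.3e-05 by edgeR. ID 925321 fell from 11.6 ± 9.30 CPM to 0.642 ± 0.357 CPM (SD, n = 3 each), with a log2 fold change of -4.16, an SE of 0.68 and an adjusted p of 0.00252 by edgeR; the log2 fold change was -3.32 without 5-month replicate 2. At 2 months this gene stood at 0.0688 CPM.

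Between 5 and 10 months 3657 genes (18.1%) changed by edgeR, 2005 higher and 1652 lower at 10 months. At least 2-fold changes numbered 1048 higher and 976 lower, and at least 8-fold changes 76 and 61. The median log2 fold change was 1.03 in the higher genes and -1.13 in the lower genes. The later libraries lay wholly above the earlier ones in 1995 of the higher genes and wholly below in 1640 of the lower genes. Of all tested genes 41.8% were separated in this way, where chance gives 10% on average. The balance of directions rested on the scaling. Upper-quartile scaling, tried after seeing the data, moved the median log2 fold change of all genes from -0.03 to -0.15 and gave 1560 higher and 2235 lower genes, or 41.1% higher in place of 54.8%. Higher genes made up 389 and lower genes 111 of the changed genes over 100 CPM, whereas under 1 CPM 53 were higher and 174 lower. With upper-quartile scaling these became 297 and 147 over 100 CPM, and 46 and 235 under 1 CPM. Between 10 and 100 CPM the lean flipped, from 1180 higher and 710 lower to 932 higher and 988 lower. Scaling to library totals alone, also tried after seeing the data, moved the median of all genes to -0.57 and gave 584 higher and 5526 lower genes (9.56% higher), with 117 higher and 335 lower over 100 CPM and 316 higher and 2272 lower between 10 and 100 CPM. The direction of the 2 more abundant classes therefore holds only relative to the scaling used, while both classes under 10 CPM had more lower than higher genes under each scaling run. The count of changed genes was 2209 without 5-month replicate 1, 2072 without 5-month replicate 2, 2063 without 10-month replicate 2 and 2167 without 10-month replicate 3. It fell to 797 without the 3 libraries in which 6 genes took over 10% of reads, which left a single 10-month library that was assumed to vary like the others.

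**Figure D3:**
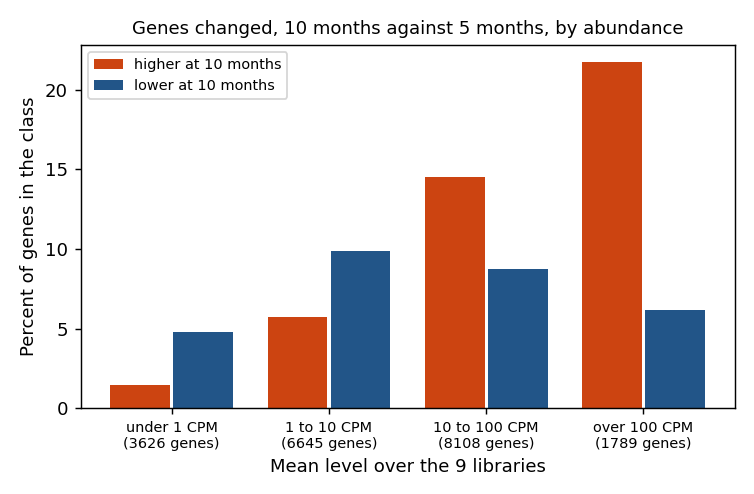
Percent of tested genes that were higher (red) or lower (blue) at 10 than at 5 months by edgeR with TMM scaling, in 4 classes of mean CPM over the 9 libraries. Higher genes outnumber lower ones in the 2 most abundant classes, but upper-quartile scaling flips the class of 10 to 100 CPM (932 higher, 988 lower), and library totals alone flip both (316 and 2272; over 100 CPM 117 and 335).

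The comparison of 10 with 2 months spanned the whole period. ID 1025303 rose from 0.112 ± 0.0694 CPM at 2 months to 176 ± 254 CPM at 10 months (SD, n = 3 each), with 8.66 ± 4.00 CPM (SD, n = 3) at 5 months. Its log2 fold change was 10.87 with an SE of 1.85 (edgeR, adjusted p = 0.00295). The size of the rise rested largely on 10-month replicate 3: the log2 fold change was 8.31 without it, and 10.17 without 2-month replicate 1. It was 9.82 on total gene reads and 12.58 without the 3 libraries in which 6 genes took over 10% of reads. The call was lost with limma voom, at a log2 fold change of 9.52 and an adjusted p of 0.115, the highest of its alternatives, which began at 2.3e-15, and 34.8% of its reads also map to other genes. ID 943714 had 1 unique read over the 2-month libraries and 2887 over the 10-month libraries, a scaled ratio of 1709 with an exact 95% counting interval of 306 to 67523. Its mean at 10 months was 15.8 ± 4.33 CPM (SD, n = 3), and edgeR gave an adjusted p of 4.1e-06. The single read was in 2-month replicate 1, so without that library the 2-month level was 0 and the ratio has no upper limit. ID 960591 was again among the falls, at 0.0710 ± 0.0563 CPM (SD, n = 3) at 10 months with a log2 fold change of -8.99 and an SE of 0.81 (edgeR, adjusted p = 3.2e-05); this was -9.82 without 10-month replicate 3 and -8.22 without 2-month replicate 1. ID 1026260 stood at 0.792 ± 0.193 CPM (SD, n = 3) at 10 months, with a log2 fold change of -8.80 and an SE of 0.66 (edgeR, adjusted p = 8.9e-06).

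Between 2 and 10 months 6685 genes (33.1%) changed by edgeR, 3532 higher and 3153 lower at 10 months. At least 2-fold changes numbered 2262 higher and 1657 lower, and at least 8-fold changes 419 and 123. The median log2 fold change was 1.24 in the higher and -1.03 in the lower genes. The higher genes included 15 with 0 unique reads in every 2-month library. There were 25 genes under 1 CPM in each 2-month library and at 10 CPM or more in each 10-month library, and 8 with the opposite change. Separation of the 3 and 3 libraries was seen in 3457 of the higher and 3000 of the lower genes. It was seen in 45.9% of all tested genes, where chance gives 10% on average. Here too the balance of directions turned with the scaling: upper-quartile scaling moved the median log2 fold change of all genes to -0.13 and gave 3074 higher and 3867 lower genes, or 44.3% higher in place of 52.8%. Library totals alone moved the median to -0.43 and gave 1687 higher and 5100 lower genes (24.9% higher). Most of these calls were not made again without the 3 libraries in which 6 genes took over 10% of reads. That fit left a single 10-month library, so an effect of those libraries cannot be told apart from the smaller number of libraries.

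Changes since 2 months overlapped between the later harvests. There were 1446 genes higher at both 5 and 10 months than at 2 months and 1270 lower at both, where independent lists would share 411 and 287. Opposite calls were made for 29 genes higher at 5 but lower at 10 months and 28 genes lower at 5 but higher at 10 months, where independent lists would give 367 and 321. The log2 fold changes of both comparisons correlated across genes at r = 0.73, against 0.53 in 20 simulations with no effect but the same shared 2-month libraries. Their covariance was 0.73 against 0.068 simulated, a difference of 0.67. Genes are not independent replicates, and part of the excess in calls may come from the shared libraries, because 3 libraries cannot be parted into groups of at least 2. The changes from 2 to 5 months and from 5 to 10 months had a covariance of -0.10 against -0.060 simulated, a difference of -0.040, with r = -0.14 against -0.49 simulated. Of genes higher at 5 than at 2 months, 519 were then lower at 10 than at 5 months, where independent lists would share 192, and 296 rose again, where 233 would be shared. Of genes lower at 5 than at 2 months, 185 then rose and 155 fell again, where 182 and 150 would be shared. These last comparisons have the 5-month libraries in common, which by itself favours opposite calls, so the counts for independent lists are not what no effect would give and no excess is read from them.

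The 5 genes with the highest mean CPM were IDs 507124, 960508, 838592, 127396 and 1018247. ID 507124 took 4.79% ± 4.62 of unique reads at 2 months, 0.683% ± 0.202 at 5 months and 6.25% ± 5.66 at 10 months (SD, n = 3 each). Its log2 fold changes, TMM-scaled unlike these shares, were -3.05 at 5 against 2 months (edgeR, adjusted p = 0.105), 3.99 at 10 against 5 months (adjusted p = 0.0567) and 0.95 at 10 against 2 months (adjusted p = 0.555). None was past the threshold in the test as planned. Testing only genes with at least 10 CPM in 3 libraries called the second of these (adjusted p = 0.0326). DESeq2 called the first and second of these (adjusted p = 0.0179 and 0.0012), as did edgeR without 10-month replicate 3 (0.0205 and 0.0072) and with only the compared harvests (0.0363 and 0.0465). Without 2-month replicate 2 the first was -1.70, and without 10-month replicate 2 the second was 2.78. Over the alternatives the adjusted p ran from 0.0179 to 0.297 for the first and from 0.0012 to 0.650 for the second. ID 838592 had log2 fold changes of -3.23, 3.57 and 0.34 in the same order, also with none past the threshold in the planned test (edgeR, adjusted p = 0.103, 0.0880 and 0.846). The second was called with only genes of at least 10 CPM in 3 libraries (adjusted p = 0.0484). For this gene, too, DESeq2 called the first and second (adjusted p = 0.0185 and 0.0083), as did edgeR without 10-month replicate 3 (0.0341 and 0.0240), within ranges of 0.0185 to 0.306 and 0.0083 to 0.768 over the alternatives. The first was -1.62 without 2-month replicate 2, and the second 2.36 without 10-month replicate 2. ID 960508 had log2 fold changes of -2.66 at 5 against 2 months (edgeR, adjusted p = 0.136) and 1.84 at 10 against 2 months (adjusted p = 0.240). Some alternatives called the first of these, among them edgeR with only the compared harvests (0.0363) and without 10-month replicate 3 (0.0271), but most did not. The gene was higher at 10 than at 5 months, with a log2 fold change of 4.50 and an SE of 1.25 (edgeR, adjusted p = 0.0376). That call was lost without any one of the 5-month libraries or without 10-month replicates 1 or 2, at adjusted p of 0.0816 to 0.160, within a range of 0.000161 to 0.977 over its alternatives. Its log2 fold change was 3.19 without 10-month replicate 2 and 0.035 without the 3 libraries in which 6 genes took over 10% of reads (adjusted p = 0.977). ID 127396 rose from 0.710% of unique reads at 2 months to 1.51% at 10 months. Its TMM-scaled log2 fold change, a different measure from these shares, was 1.55 with an SE of 0.33 (edgeR, adjusted p = 0.00315). With library totals alone it was 1.09. At 10 against 5 months its log2 fold change was 1.12 with an SE of 0.32 (edgeR, adjusted p = 0.0307), a call lost without 5-month replicates 1 or 2 or 10-month replicates 2 or 3 at adjusted p of 0.0796 to 0.122, within a range of 0.00132 to 0.226 over its alternatives. The highest of these came with library totals alone, at a log2 fold change of 0.53. ID 1018247 passed the threshold in none of the 3 comparisons by edgeR, with log2 fold changes of 0.41, 0.16 and 0.56 (adjusted p = 0.415, 0.780 and 0.213).

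The first 3 of these genes varied together between libraries, along with IDs 838638, 960513 and 838596, which were singled out after their values were seen because they correlated with ID 507124 at r over 0.95 across the 9 libraries. Together the 6 genes took 6.84%, 24.9% and 3.35% of unique reads in the 2-month libraries, 1.39%, 1.47% and 2.30% in the 5-month libraries, and 17.2%, 31.9% and 1.24% in the 10-month libraries. Their mean share was 11.7% ± 11.6 at 2 months, 1.72% ± 0.502 at 5 months and 16.8% ± 15.3 at 10 months (SD, n = 3 each). Each 2-month library lay above each 5-month library, whereas the 10-month libraries overlapped both other harvests. The two-sided exact permutation p was 0.1 for 5 against 2 months, 0.4 for 10 against 5 months and 0.7 for 10 against 2 months. As 3 libraries against 3 cannot go below 0.1, this test could not call a difference between harvests.

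**Figure D4:**
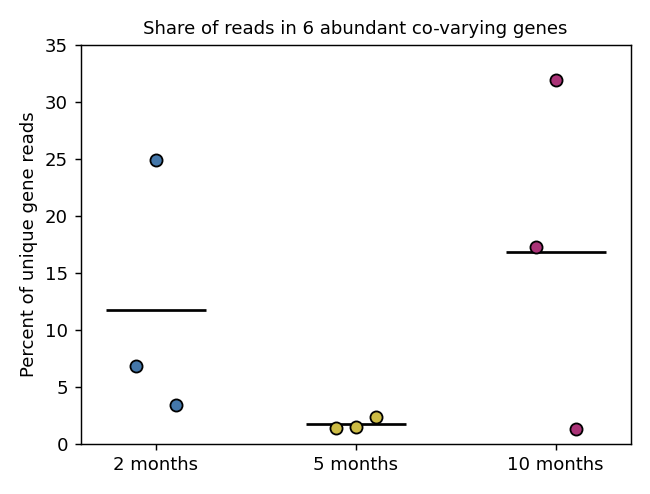
Percent of unique gene reads in the 6 co-varying abundant genes, 1 point per library, with a line at the mean of each harvest. The 5-month libraries lie between 1.39% and 2.30%, while the 10-month libraries range from 1.24% to 31.9%.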

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

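All tests of genes with mostly shared reads were chosen after the result was seen. Reads that map to more than 1 gene lie outside the counts compared in the report and were present in every library, so they were singled out as data not otherwise used. They made up between 1.20% of total gene reads in 10-month replicate 2 and 2.22% in 5-month replicate 1. Their mean share was 1.64% ± 0.194 at 2 months, 1.90% ± 0.496 at 5 months and 1.64% ± 0.424 at 10 months (SD, n = 3 each).

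When total gene reads were tested in their place, 337 tested genes had at least 50% of their reads shared with other genes, and 82 of these had no unique read at all. Over the 3 harvests 39.8% of them changed by edgeR against 38.4% of the other 20013 tested genes (Fisher's exact test, two-sided, p adjusted over 2 tests = 0.611). Between 2 and 5 months 63 of them rose and 28 fell, so 69.2% of the changed ones were higher, against 55.7% among other genes (Fisher's exact test, two-sided, adjusted p = 0.0205). This test restates the lean that prompted it, on the same counts, so it cannot count as evidence for it. It also did not allow for abundance. Within 4 classes of mean CPM the odds ratio was 1.60 (exact 95% interval 0.996 to 2.63), with an exact p of 0.0706 adjusted over the 3 comparisons of harvests. In the same within-class test the odds ratio for being higher at the later harvest was 1.65 at 10 against 2 months (1.07 to 2.57, adjusted exact p = 0.0555) and 0.854 at 10 against 5 months (0.460 to 1.56, adjusted exact p = 0.668), so no comparison passed the threshold. Genes that share reads are also not independent, which makes each p too small. What these genes encode is not known here, and whether they lean at all beyond their abundance stays open.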

How the results depend on the processing

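Upper-quartile scaling, library totals alone, total gene reads, thinning, leaving out the 6 abundant genes and leaving out 2 or 3 libraries were chosen after seeing the data. Of 94 alternative counts of changed genes 80 were within 1.5 times the reported count. Among the reported calls still tested in an alternative, at least 98.0% kept their direction in each. Fewer were called again: at 10 against 5 months 55.1% without 10-month replicate 2, and 61.1% with library totals alone. Without 3 libraries most calls at 10 against 5 and 10 against 2 months were not made again, in a fit with 1 library at 10 months. Library totals alone gave 6110 changed genes at 10 against 5 months, by moving the fold of all genes. Testing only genes with at least 10 CPM in 3 libraries, which removes genes by construction, gave 2539 changed genes at 5 against 2 months and 5099 over the 3 harvests. A 2-fold minimum, also stricter by construction, gave 2457 at 5 against 2, 2024 at 10 against 5 and 3919 at 10 against 2 months. Without the 3 libraries with the highest share of the 6 genes (2-month replicate 2 and 10-month replicates 1 and 2) the counts were 797 at 10 against 5 months, 2212 at 10 against 2 months and 3521 over the 3 harvests; fewer libraries were compared, and the lone 10-month library was assumed to vary like the others. With each library left out in turn the counts ran from 2772 to 4053 at 5 against 2, 2063 to 3982 at 10 against 5, 4998 to 6775 at 10 against 2 months, and 5985 to 7512 over the 3 harvests. DESeq2 called 5216, 4697, 7484 and 9198 genes in that order, with an adjusted p of NA for 10 genes, and limma voom 4078, 3918, 6556 and 7944. No sign was seen that replicate numbers pair the libraries, though a weak pairing could be missed. Deviations of log2 CPM from the harvest mean correlated across genes at -0.205 to 0.116 in 9 same-numbered pairs, 1 of them over 0.1. By these deviations 0 of 9 libraries correlated best with their own number. With the replicate block the counts were 3113, 2581, 5686 and 6130, and IDs 127396 and 960508 missed the threshold at 10 against 5 months (adjusted p = 0.0506 and 0.0910). Reversed log2 fold changes, all of abundant genes, were these, and the cause was not tested. Without the 3 libraries ID 507124 had -0.47 at 10 against 5 months and -2.16 at 10 against 2 months, the latter called in the opposite direction (adjusted p = 0.0410); ID 838592 had -0.38 and -1.99, and ID 960508 -1.43 at 10 against 2 months. Without 10-month replicate 2 ID 507124 had -0.26 and ID 838592 -0.86 at 10 against 2 months, and ID 1018247 -0.065 at 10 against 5 months, as it had without the 2 libraries with the highest share. Without 5-month replicate 3 ID 1018247 had -0.053 at 10 against 5 months, and without 2-month replicate 3 ID 838592 had -0.15 at 10 against 2 months. With library totals alone ID 1018247 had -0.43 at 10 against 5 and ID 838592 -0.21 at 10 against 2 months. With single libraries left out the highest values of these results were 0.51 for ID 1018247, 2.29 for ID 507124 and 1.95 for ID 838592. Named genes chosen by size of change kept their call in 264 alternative fits and lost it in 10. Among these genes ID 952265 lost it most often, ID 925321 missed it without the 3 libraries and ID 1025303 with voom. Abundant genes gained 21 calls in the same direction, besides the reversed one, and lost 19. Gene list tests were not run, nor were the pseudocount and filter alternatives meant for normalized values. Depth limits the genes near the floor of 3 reads most at 2 months.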

Other observations

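The tests of harvest month and of shared reads for the 6 abundant genes, and the second test of an even background, were chosen only after the result was seen. The 6 abundant co-varying genes took from 1.24% to 31.9% of unique reads, and the range was wide inside a single harvest. Harvest month alone would need libraries of one month to differ less than the months do. The largest fold between libraries of one month was 25.6, against 9.75 between month means. Folds of single libraries and of means are unlike measures, and the genes were picked after their values were seen. The test thus restates the spread within a month, which by itself argues against month as the only source of the variation. Reads shared between near-identical copies are also argued against, since at most 0.000986% of the reads of any of the 6 genes mapped elsewhere. The criterion written for that test set the median share in the 6 genes against that of all tested genes, which was 0. By it the 6 genes fell on the side of shared reads. The verdict rests instead on how small their shares were. Differences between single microcosms and differences in library preparation stay open, as no label records either, and what the 6 genes encode is not known here. With the 6 genes left out of the counts before TMM scaling, 97.1% of the genes called between 5 and 10 months were called again. This bears only on the counts of these genes under that scaling. It does not show how far the libraries rich in them affected the calls.

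Between 5 and 10 months abundant genes leaned upward relative to rare genes, whichever way the classes leaned under a given scaling. Spearman's rho across 20168 genes, between the log2 fold change and the level at 2 months, which enters neither side of the comparison, was 0.21; genes are not independent replicates, so no p is given. It lay between 0.12 and 0.22 for each of 9 pairs of 1 library per harvest, against sizes of 0.020 to 0.10 for 6 pairs within a harvest. Depth alone is argued against, since rho was 0.20 with the libraries thinned to one depth, and so are the libraries rich in the 6 abundant genes, since rho was 0.20 in the 10-month library with the lowest share of them. Transcript length stays open as part of it: rho was 0.17 to 0.24 within 4 length classes of equal size, and the lowest of these cleared the bound set before by less than its own spread.

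An even background of reads over all genes at 5 months could also give that lean, and 2 tests of it did not settle this. The test fixed first divided the median drop in scaled RPKM from 5 to 10 months in the 5th of 10 equal classes of genes, ranked by 2-month level, by that in the 2nd class; a ratio under 2 was to count for a background and one over 5 against it. The ratio was 1.23, on the side set for a background. Scaling sets where the drop passes through 0, and the 5th class lies near that point (median drop 0.158 RPKM, against -0.0612 in the 6th). A low ratio can therefore arise without a background, and this one counts for neither side. For that reason a second test was added after the ratio was known. It found the median drop larger in the 4th than in the 1st class by 0.197 RPKM (95% bootstrap interval over genes 0.142 to 0.240, 2000 resamples), which a perfectly even background would not give. The second test was picked with the first result in hand, and its interval covers spread over genes, not libraries. A background at 5 months would also favour the opposite lean at 5 against 2 months. There rho with the 10-month level was -0.069, and at 10 against 2 months rho with the 5-month level was 0.099. Both sizes lay within the 0.020 to 0.10 seen within a harvest. That range came from pairs of single libraries ranked by 2-month level, an unlike measure to means of 3 libraries, so it sets no bound here. The rho of -0.069 has the sign of a background but is smaller in size than 0.21. Changed genes under 1 CPM leaned the same way at 5 against 2 months, with 307 higher and 80 lower. Over 100 CPM 256 were higher and 137 lower, so that lean was not confined to rare genes. The 5-month level enters these classes. A background of reads at 5 months, like a change in the fungus between harvests, stays open. GC content and RNA integrity were not tested, as no sequences or integrity values were used here.

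Regrouping the libraries bears on whether the counts of changed genes arose by chance. For any difference over the 3 harvests, 1 of 60 groupings drawn from 280 reached the real count of 7746, the real one itself. The highest of the others gave 1738. A share of groupings under 0.05 had been set beforehand to count against chance. The share was under that, which argues against chance for this count but does not exclude it. Groupings not drawn were not run. The others drawn mixed libraries of different harvests, so 1738 is not the count that no difference would give. With 3 against 3 libraries there are only 10 groupings, too few for a share under 0.05. For 5 against 2 months the real grouping gave 4180 genes, for 10 against 5 months 3657 and for 10 against 2 months 6685. The highest of the other groupings gave 0 genes by edgeR and 0 by limma voom in each comparison, with at most 1497, 1366 and 995 genes at an unadjusted p under 0.05 by edgeR, where the real groupings gave 7048, 6453 and 8712. In each of the 3 comparisons 1 grouping, the real one, reached the real count. Every other grouping mixed libraries of both harvests, so a real difference would widen its spread and lower its calls. Its 0 calls are therefore not the count that no difference would give. Regrouping also cannot part harvest from library preparation or depth, where these went with harvest.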
